A study of Mus musculus with 6 samples.

How the data were processed

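RNA-seq counts of mouse long-term haematopoietic stem cells (LT-HSCs) were analysed for 6 libraries in 4 groups. The groups were wild-type (WT) naive (1 library), WT infected (2 libraries), Dnmt3a knockout (Dnmt3a KO) naive (1 library) and Dnmt3a KO infected (2 libraries), each assigned from the sample labels. Infected mice had carried Mycobacterium avium for 1 month and naive mice had received PBS, per the labels. The sorting gate, the number and sex of the animals behind each library and the kit's strand setting are not given in the sources used here. Because the labels do not say that the libraries came from separate animals, p-values measure only the spread between these samples, which may be technical.

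Total counts ran from 1279856 to 7666217 per library, and the shallower libraries give less precise values. The values are raw counts per gene, which the authors deposited as 1 column per library. Per the labels, total RNA was extracted with a NucleoSpin RNA Plus XS kit and made into libraries with standard Illumina methods. Per the deposited workflow text, paired-end reads passed through HTStream 1.1.0, which screened PhiX and ribosomal RNA, removed PCR duplicates, trimmed adapters and low-quality ends and dropped fragments under 50 bases. Reads were then aligned with STAR 2.7.0e to the GRCm38 primary assembly with GENCODE M22 genes, and STAR counted reads per gene. The submitters' processing notes name STAR, limma and GRCm38.p6. Which of STAR's strand columns was kept is not given in the sources used here, so counts of overlapping and antisense genes are uncertain. Duplicate removal without molecular identifiers can lower the counts of short, abundant transcripts, and reads that match near-identical copies, such as members of the Gbp, Tgtp, H2, Csf2rb and Hspa1 families, may be lost or divided between them. Counts per gene also do not separate exons, so a transcript left after a deletion of some exons is still counted.

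The table held 55573 genes, of which 55394 were matched to a symbol by Ensembl gene identifier. Coordinates came from GENCODE M21 on GRCm38, 1 release before the authors' annotation, and were used only for the 55180 identifiers with the same version there. Genes were tested when they reached 3.41 CPM (counts scaled by library size), equal to 10 counts in the median library, in at least 2 libraries and at least 15 counts in all, which left 12056 genes. A gene that reached this level in 1 naive library alone was left out, which can favour genes called higher with infection. Normalisation factors came from the trimmed mean of M values (TMM) in edgeR 4.0.16 on R 4.3.3, and CPM values are TMM-scaled. A model with 1 mean per group was fitted with edgeR's quasi-likelihood method (glmQLFit with legacy=FALSE, set explicitly, after estimateDisp). With 2 residual degrees of freedom, the spread came from the infected pairs and from sharing between genes (prior degrees of freedom 15.7, biological coefficient of variation 0.207), so each lone naive library is assumed to vary like the infected pairs. In all parts, "edgeR adjusted p" means the quasi-likelihood F test with Benjamini-Hochberg adjustment over the 12056 genes and a threshold of 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F.

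The 7 comparisons were infection within each genotype, genotype among infected and among naive libraries, the difference of the infection responses, and the mean infection and mean genotype effects. Between the naive libraries, 1 against 1, differences are described with exact Clopper-Pearson 95% intervals of each library's count and no p-value is given for a single gene; only counts of calls are given, from the fit that borrows the spread of the infected pairs. These intervals, and the floor of 3 counts per library used for a fold against a group at 0, cover counting error only. Gene lists with at least 5 measured members (26 lists) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated, and with fry, which asks whether the members move 1 way on balance without comparing them with other genes. "Camera adjusted p" is adjusted over the 26 lists of a comparison. With the correlation estimated, camera rests on the 2 residual degrees of freedom, so its p-values rarely become small. A call lost in that test does not show that a list was unchanged. T and NK cell markers (3 measured), B and plasma cell markers (3), macrophage markers (4) and mast cell and basophil markers (2) had too few measured members for a list test. Between the naive libraries, the median of each list was ranked among 10000 random lists of the same size, matched on mean expression. Members of a list may vary together and random genes do not, so these percentiles are a description and not a test.

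The grouping, tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. Named genes were the 2 passing members with the smallest p in each list, the 5 largest passing changes in each direction at a mean of at least 5 CPM whose libraries did not overlap, and a fixed panel of 12 genes, 1 of which is not reported here. For the difference of responses the 5 smallest p on each side were taken, and for the naive libraries the 5 largest differences in each direction at a mean of at least 20 CPM. Symbols of unnamed genes and pseudogenes were left out of the ranking by size.

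Alternatives were DESeq2 1.42.0, limma voom, edgeR with legacy=TRUE, DESeq2 size factors, library totals alone, no filter, a stricter filter, a 1.5-fold threshold with glmTreat, an additive model, the compared groups alone, replicate numbers as a block, and each library left out in turn. A voom fit with the filter in the deposited workflow text (highest CPM of at least 3) and counts thinned to the shallowest library were added after the data were seen. The pipeline was tested on simulated counts with known changes. At 4-fold it recovered 61.6% of changed genes for infection in WT, 83.9% for infection in Dnmt3a KO, 75.4% for genotype among infected libraries and 35.2% for the difference of responses, and at 2-fold 21.7%, 20.8%, 29.4% and 7.81%. Unchanged genes called in those simulations numbered 2, 17, 6 and 3 in the same order, and 6 between naive libraries; the 17 were 11.8% of the calls for infection in Dnmt3a KO, above the threshold of 5%, as were the 6 between naive libraries at 6.12%. With no changes simulated, edgeR made 0 calls in each of the 7 comparisons. The simulated spread was set by expression level and was the same in every library. The simulations held no library that stands apart, so error and recovery in these data may differ.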

Results

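Transcripts of LT-HSCs, the rare cells that sustain blood formation in the long term, were counted in C57BL/6 mice that were WT or lacked Dnmt3a, a DNA methyltransferase that places new methyl marks. Mice were naive or had been infected for 1 month with M. avium, a slow-growing bacterium that causes chronic infection. WT naive and Dnmt3a KO naive were represented by 1 library each, and WT infected and Dnmt3a KO infected by 2 each. Total counts were 5755941 for WT naive, 1279856 and 1693884 for WT infected 1 and 2, 2813429 for Dnmt3a KO naive, and 3060113 and 7666217 for Dnmt3a KO infected 1 and 2. The infected replicates differed by more than sampling noise, with a chi-square per gene of 7.25 in WT and 8.01 in Dnmt3a KO, where noise alone gives about 1. Chi-square grows with depth, and the WT pair was shallower. The SD of the log2 difference across genes, which also holds counting noise, was 1.13 in the WT pair and 0.458 in the Dnmt3a KO pair. The Pearson correlations of log2 CPM were 0.879 and 0.972.

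The libraries differed in other ways than their group. Small and structural RNA classes took 11.8% of counts in both WT infected libraries and 4.97% to 6.50% in the other 4. These classes include the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, at 5.31% and 5.35% in WT infected 1 and 2 and 2.64% to 3.79% elsewhere. The unnamed genes Gm26917, Gm23935 and Gm42418 together took 13.2% and 12.3% in WT infected 1 and 2 and 5.55% to 8.59% elsewhere. WT infected 1 stood apart at 2.83 on the first axis of a multidimensional scaling plot, which carried 52.8% of the variance, while the other libraries lay between -0.80 and -0.32. Xist, transcribed from the inactive X chromosome of female cells, lay between 551 and 1232 CPM, and Uty, a Y chromosome gene, between 11.9 and 30.0 CPM, so both were counted in every library. With the animals' sex not given, a change of Xist below cannot be assigned to infection or to genotype.

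Dnmt3a (ENSMUSG00000020661.15, GRCm38 chromosome 12, 3806007 to 3914443) was lower in each Dnmt3a KO library than in each WT library. It stood at 177 CPM in WT naive (95% interval 166 to 187), 263 and 198 CPM in WT infected 1 and 2, 99.4 CPM in Dnmt3a KO naive (88.2 to 112), and 69.6 and 62.8 CPM in Dnmt3a KO infected 1 and 2. The mean genotype effect was a log2 change of -1.31 ± 0.17 (SE, edgeR adjusted p = 0.00022), which kept its call in all 11 alternatives (adjusted p 4.6e-12 to 0.027). Transcripts of the gene therefore remained countable in the knockout. Infection did not change Dnmt3a by the test in WT (log2 0.38 ± 0.23, edgeR adjusted p = 0.58) or in Dnmt3a KO (log2 -0.60 ± 0.24, edgeR adjusted p = 0.80).

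The first comparison asked how WT LT-HSCs respond to infection. Genes of the interferon response rose. Irf1 (ENSMUSG00000018899.16, chromosome 11, 53770014 to 53778374), a transcription factor gene induced by interferon, went from 80.4 CPM to 291 ± 0.634 CPM (mean ± SD, n = 2), a 3.62-fold rise (log2 1.85 ± 0.23, edgeR adjusted p = 6.1e-05). Iigp1 (ENSMUSG00000054072.12, chromosome 18, 60376027 to 60392634), a GTPase that attacks the vacuoles of intracellular microbes, rose 9.28-fold from 86.1 to 800.2 ± 71.3 CPM (log2 3.21 ± 0.24, edgeR adjusted p = 3.3e-07). The chemokine gene Cxcl9 (ENSMUSG00000029417.9, chromosome 5, 92321347 to 92328079), which attracts T cells, had 0 counts in WT naive and 84.6 ± 31.3 CPM in WT infected, at least 173-fold higher.

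Of 20 interferon-inducible GTPases, 17 rose in WT (19 adjusted over the list alone), with a median log2 change of 2.43, and none fell; Gbp2 rose 7.48-fold and Gbp4 13.4-fold. Among 42 interferon-stimulated genes 15 rose and 27 did not pass (27 rose adjusted over the list alone), including Ly6a, which encodes the stem cell surface marker Sca-1 and rose 4.69-fold. MHC class I presentation genes rose in 13 of 21 cases (20 adjusted over the list alone), among them the peptide transporter gene Tap1 at 2.41-fold and the immunoproteasome gene Psmb10 at 3.44-fold. MHC class II genes, which present peptides to helper T cells, rose in 5 of 11 cases (8 adjusted over the list alone). H2-Ab1 (ENSMUSG00000073421.6, chromosome 17, 34257689 to 34269419) rose 10.7-fold to 808 ± 16.7 CPM and Cd74 (ENSMUSG00000024610.15, chromosome 18, 60803848 to 60812652) 9.97-fold to 692 ± 79.4 CPM. All 4 lists kept their camera call with an estimated correlation (camera adjusted p 0.029 for the GTPases, 0.040 for interferon-stimulated and class II genes, and 0.044 for class I genes). WT naive was the lowest of the 6 libraries for 17 of the 21 class I genes, 8 of the 11 class II genes, 16 of the 42 interferon-stimulated genes and 7 of the 20 GTPases; for a gene higher in every infected library, only a naive library can be lowest.

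**Figure D1:**
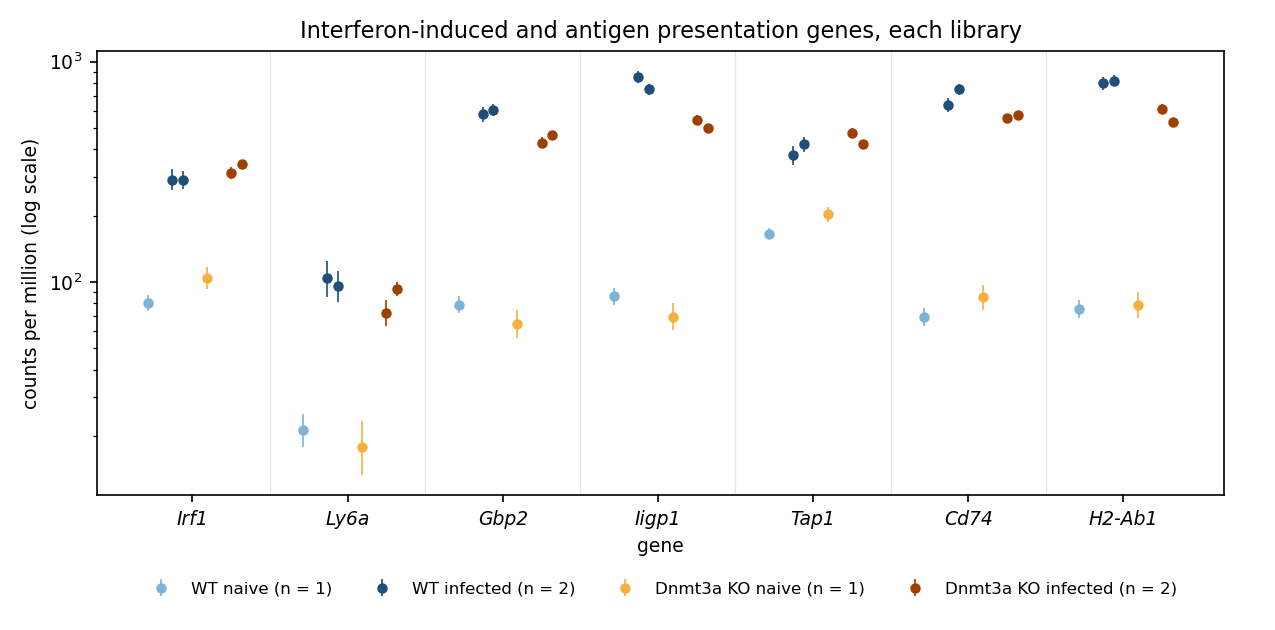
Normalised counts (CPM, log axis) of 7 interferon-response genes in each of the 6 libraries, with 95% counting intervals as bars. For Iigp1 the 4 infected libraries lie between 501 and 851 CPM, above both naive libraries at 86.1 and 69.7 CPM.

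A second set of genes rose in WT. Immediate early and stress genes, which switch on within minutes of stimulation or tissue dissociation, rose in 20 of 28 cases (24 adjusted over the list alone), with a median log2 change of 1.70 (camera adjusted p = 0.029 with an estimated correlation). Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273), a subunit of the AP-1 factor, rose 7.73-fold from 88.6 to 687 ± 93.8 CPM (log2 2.95 ± 0.24, edgeR adjusted p = 6.5e-07). Atf3 rose 36.4-fold, Nr4a1 9.25-fold and Klf2 8.98-fold. Neutrophil genes rose with them: all 7 measured neutrophil markers passed, S100a9 at 17.0-fold and Ngp at 18.4-fold, although camera adjusted p = 0.075 with an estimated correlation. The log2 change of Ngp, 4.2, was 3.55 without WT infected 1 and 5.32 at the thinned depth. Among 20 myeloid progenitor genes 6 rose (9 adjusted over the list alone, with 1 lower; camera adjusted p = 0.049 with an estimated correlation), led by Mpo (ENSMUSG00000009350.13, chromosome 11, 87793581 to 87804413), which encodes myeloperoxidase and went from 18.7 to 177 ± 18.1 CPM. The cytokine receptor gene Csf2rb, which has a near-identical copy, rose 12.8-fold. WT naive was the lowest library for 25 of the 28 immediate early genes, 7 of the 7 neutrophil markers and 10 of the 20 myeloid genes.

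In all, 182 of 12056 genes changed in WT, 172 higher and 10 lower, and 1305 had an unadjusted p under 0.05. Of the 182, 148 were protein coding and 34 were not, with 1 of these 34 lower. Both WT infected libraries also held the high share of small RNA classes given above, so a part of these calls may not be a response to infection. The excess of higher genes was much smaller without WT infected 2, where WT infected 1 is the only WT infected library. The fit without WT infected 1 also leaves 1 WT infected library and kept most of that excess. WT infected 1 is the library that stood apart on the scaling plot. Genes that fell included Hlf, a transcription factor gene of stem cells (2.07-fold lower, edgeR adjusted p = 0.013), and Dlg2 (6.95-fold lower, edgeR adjusted p = 0.0028), a scaffold gene whose log2 change went from -2.80 to -3.91 without WT infected 2. The call for Hlf was lost without Dnmt3a KO infected 1 or Dnmt3a KO infected 2 (adjusted p over 12 alternatives 1.1e-05 to 0.10). The count of 182 became 1217 without WT infected 2, 118 without Dnmt3a KO infected 1 and 96 without Dnmt3a KO infected 2. Scaling by library totals alone, which put the median of all genes at -0.32, gave 115 higher and 55 lower. Xist was also among the genes called higher (log2 1.01 ± 0.22, edgeR adjusted p = 0.020), a call lost under library totals and without Dnmt3a KO infected 2 (adjusted p over 12 alternatives 3.6e-06 to 0.11).

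The same question was then asked in Dnmt3a KO, where interferon genes again rose. Iigp1 went from 69.7 to 523 ± 32.1 CPM (n = 2), a 7.50-fold rise (log2 2.91 ± 0.25, edgeR adjusted p = 3.3e-06). Gbp2 rose 6.92-fold to 448 ± 26 CPM, H2-Ab1 7.24-fold to 571 ± 57.4 CPM and Cd74 6.59-fold to 563 ± 14.3 CPM. Cxcl9, with 1 count in Dnmt3a KO naive, had a ratio of 196 (counting interval 35.1 to 7747), and voom ended its call (adjusted p over 12 alternatives 2.3e-14 to 0.16).

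By list, 15 of 20 interferon-inducible GTPases rose in Dnmt3a KO (18 adjusted over the list alone), 12 of 42 interferon-stimulated genes (24) and 5 of 11 MHC class II genes (9), with estimated-correlation camera adjusted p of 0.036, 0.045 and 0.042. Of 21 MHC class I genes 1, Tap1, rose by the test over all genes (16 adjusted over the list alone), and the class I call was lost, with adjusted p = 0.061 with an estimated correlation. Tap1 rose 2.20-fold (edgeR adjusted p = 0.015), but lost its call without Dnmt3a KO infected 1, without Dnmt3a KO infected 2 and at the thinned depth (adjusted p over 12 alternatives 8.1e-06 to 0.28). The immediate early list was not called (0 rose, 1 fell; 3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.075). Its member that fell was Nr4a1, an orphan nuclear receptor gene (ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795), from 1089.5 to 472 ± 11.1 CPM (log2 -1.21 ± 0.21, edgeR adjusted p = 0.0068). Mpo did not pass (log2 -0.90 ± 0.20, edgeR adjusted p = 0.064), but was called lower under voom with either filter, without WT infected 1 and without WT infected 2 (adjusted p over 12 alternatives 0.0021 to 1.00). No neutrophil marker passed by edgeR over all genes (1 fell adjusted over the list alone; adjusted p = 0.35 with an estimated correlation).

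Altogether 57 genes changed in Dnmt3a KO, 50 higher and 7 lower, with 642 at an unadjusted p under 0.05. Of the 57, 54 were protein coding and 3 were not. The count became 156 without WT infected 1, 159 without WT infected 2, 36 without Dnmt3a KO infected 1 and 25 without Dnmt3a KO infected 2. Nr4a1 lost its call without Dnmt3a KO infected 1 and without Dnmt3a KO infected 2 (adjusted p over 12 alternatives 4.2e-09 to 0.41).

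The responses of both genotypes were compared across genes and by a test of their difference. Across 12056 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.292 and a Spearman correlation of 0.220; these comparisons share no library. Of the genes called higher, 48 were shared, where independent lists of 172 and 50 would share 0.713, and 3 of the genes called lower were shared against 0.0058. The difference of responses did not pass for the interferon genes of the fixed panel, with log2 differences of -0.11 ± 0.31 for Gbp2, -0.60 ± 0.31 for Cd74 and 0.01 ± 0.45 for Ly6a (edgeR adjusted p = 0.997 for Gbp2 and Cd74 and 0.999 for Ly6a). At these errors a modest difference was not detectable.

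**Figure D2:**
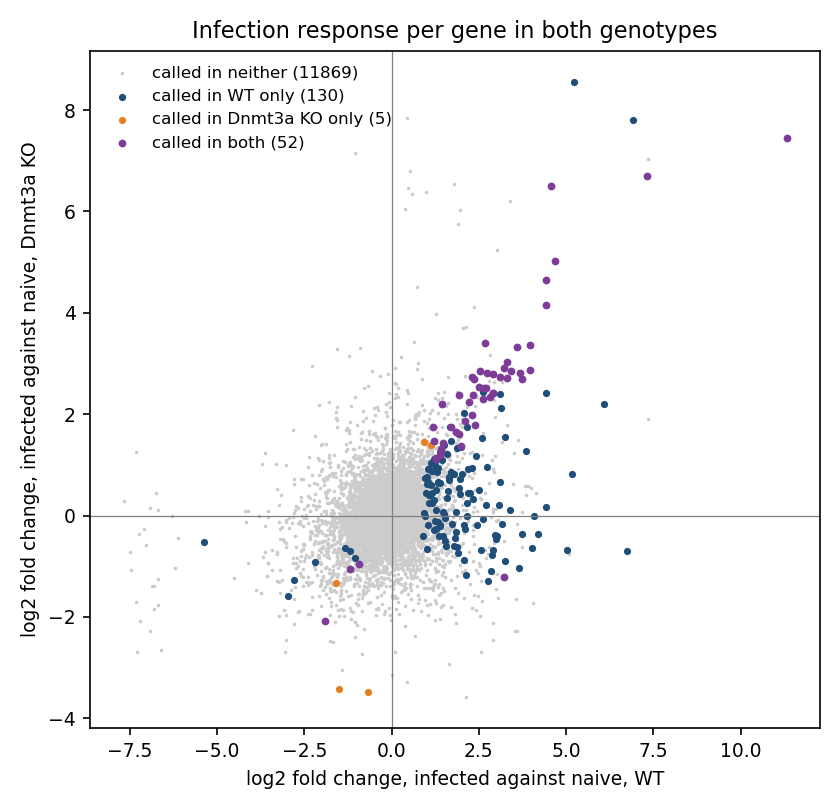
Log2 change with infection in WT (x axis) against Dnmt3a KO (y axis), 1 point per gene, coloured by where the gene was called. Of 12056 genes, 52 were called in both genotypes, 130 in WT alone and 5 in Dnmt3a KO alone, which does not test the difference between them.

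The test of the difference called 35 genes, each with a response below that of WT in Dnmt3a KO, and 0 above, with 477 at an unadjusted p under 0.05 by edgeR. DESeq2 called 36 below and 0 above (189 unadjusted), and voom 73 below and 0 above (557 unadjusted). Immediate early genes formed the largest group: 13 of 28 differed (23 adjusted over the list alone), with a median log2 difference of -1.76 (camera adjusted p = 0.045 with an estimated correlation). Nr4a1 had a log2 difference of -4.42 ± 0.36 (edgeR adjusted p = 3.1e-06) and Fos one of -3.34 ± 0.30 (edgeR adjusted p = 1.0e-05). Neutrophil and myeloid genes differed too, Mpo by -4.14 ± 0.34, S100a9 by -4.09 ± 0.51 and Ngp by -4.57 ± 0.54 on the log2 scale (for Ngp -3.91 without WT infected 1 and -5.74 at the thinned depth). Of 7 neutrophil markers 5 passed (7 adjusted over the list alone), as did 4 of 20 myeloid progenitor genes (4), and adjusted p = 0.087 for both lists with an estimated correlation. Of the 35 genes 30 were also called between the naive libraries, and this test rests on the lone naive libraries: Fos stood at 88.6 CPM in WT naive and 868 CPM in Dnmt3a KO naive, against 687 ± 93.8 and 661 ± 24.4 CPM in the infected groups. The count of 35 became 54 without WT infected 1, 168 without WT infected 2 (61 above and 107 below) and 8 without Dnmt3a KO infected 2.

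**Figure D3:**
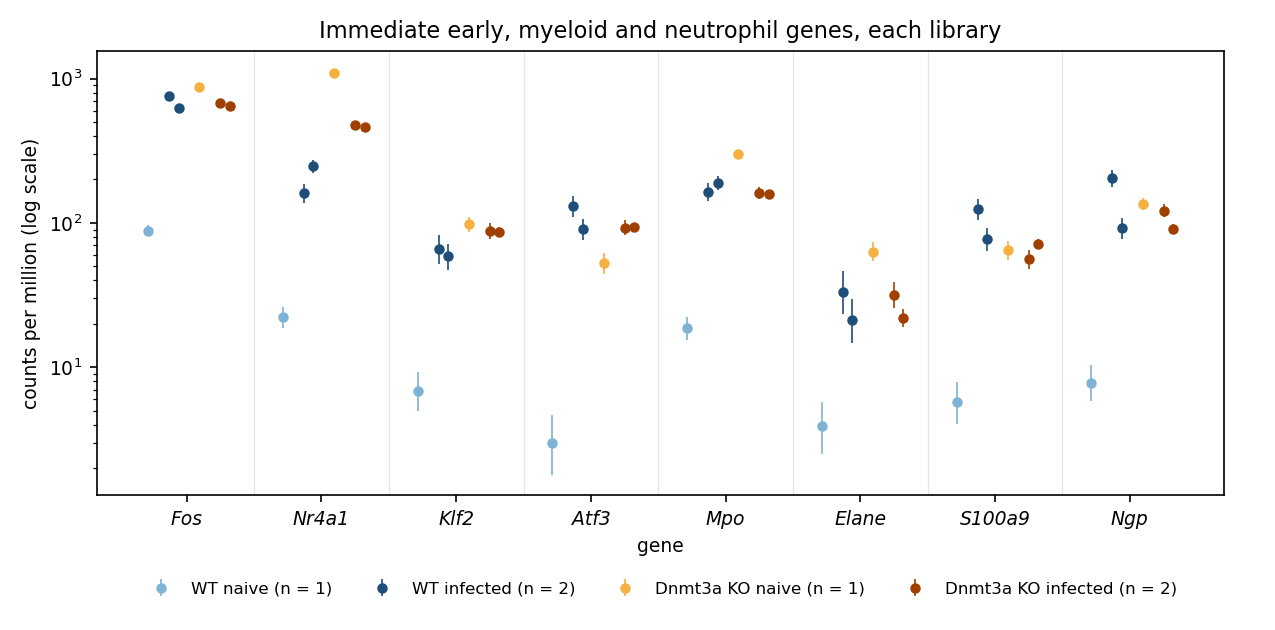
Normalised counts (CPM, log axis) of 4 immediate early genes and 4 neutrophil or myeloid genes in each of the 6 libraries, with 95% counting intervals as bars. WT naive is the lowest library for each, for example 18.7 CPM for Mpo against 298 CPM in Dnmt3a KO naive.

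Averaged over both genotypes, infection raised antigen presentation and interferon genes and lowered several stem cell genes. Irf8, which directs monocyte and dendritic cell fates, rose 6.19-fold (log2 2.63 ± 0.36, edgeR adjusted p = 0.00024). Hlf (ENSMUSG00000003949.16, chromosome 11, 90336536 to 90390895) fell 1.93-fold (log2 -0.95 ± 0.15, edgeR adjusted p = 0.0011), from 433 CPM in WT naive and 336 CPM in Dnmt3a KO naive to 207 ± 49.7 and 187 ± 1.52 CPM. Txnip, which restrains glucose uptake and is high in resting stem cells, fell 1.91-fold (edgeR adjusted p = 0.00044), and Car1, the carbonic anhydrase gene of early red cells, fell from 50.6 and 65.1 CPM in WT and Dnmt3a KO naive to 12.6 ± 7.63 and 15 ± 1.64 CPM (edgeR adjusted p = 0.0002). Hlf, Txnip and Car1 kept these calls in all 11 alternatives. Of 35 stem cell identity genes 5 fell (10 adjusted over the list alone) and none rose, with a median log2 change of -0.22 (-0.36 under library totals and -0.37 without WT infected 1) and adjusted p = 0.10 with an estimated correlation.

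For the mean response, 18 of 20 GTPases, 21 of 42 interferon-stimulated genes, 17 of 21 class I genes and 8 of 11 class II genes rose (18, 34, 21 and 11 adjusted over the lists alone), and each list had a camera adjusted p of 0.030 with an estimated correlation. The proliferation gene Mki67 did not pass (log2 0.33 ± 0.14, edgeR adjusted p = 0.36). In all 226 genes changed, 176 higher and 50 lower. Library totals alone, which shifted the median of all genes to -0.13, gave 143 higher and 88 lower. The excess of higher genes was also smaller without WT infected 2. The count became 393 without WT infected 1, 990 without WT infected 2, 122 without Dnmt3a KO infected 1 and 100 without Dnmt3a KO infected 2.

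**Figure D4:**
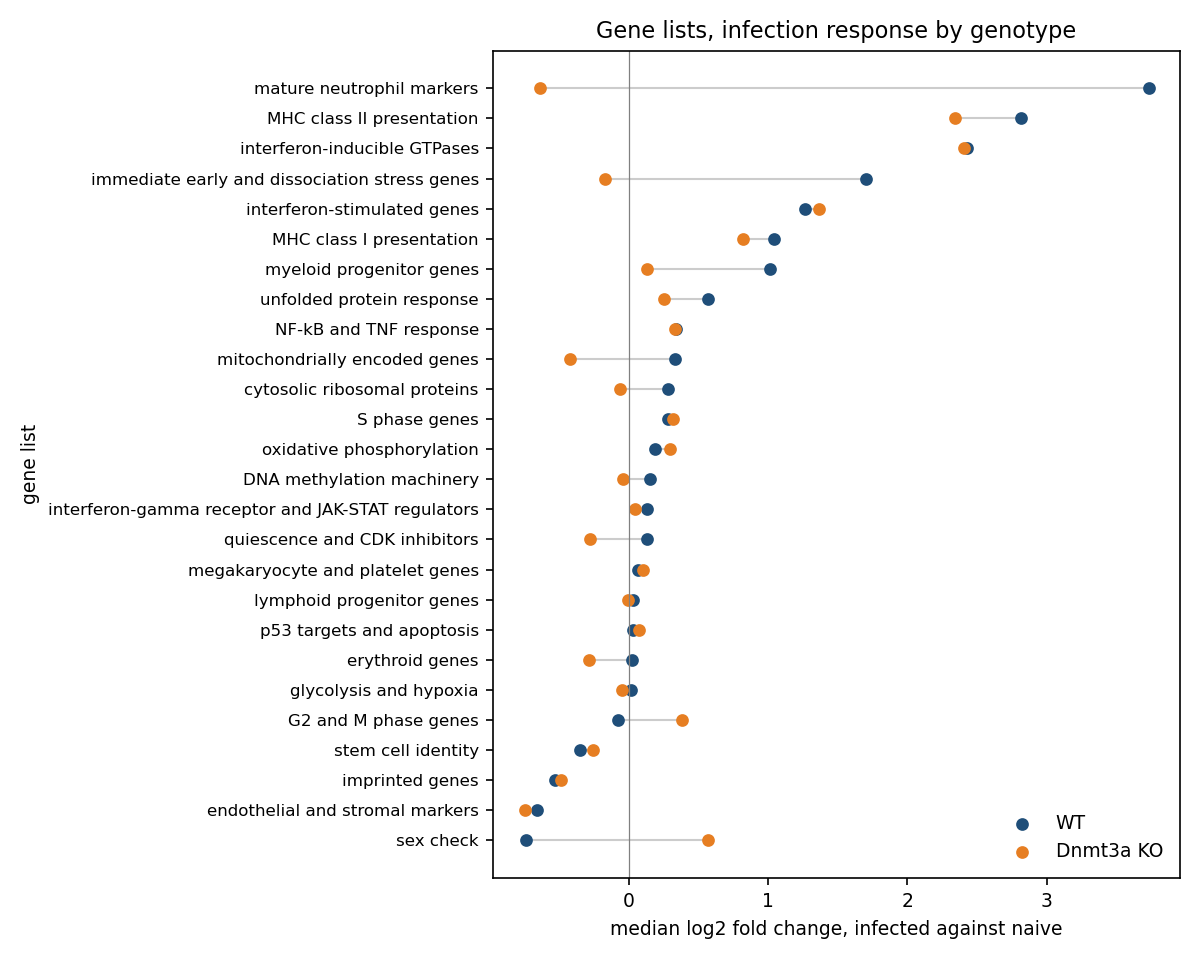
Median log2 change with infection of 26 gene lists in WT and in Dnmt3a KO. The GTPases lie at 2.43 and 2.41, and the neutrophil markers at 3.73 and -0.64.

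Genotype was compared among infected libraries, the only comparison with 2 libraries on both sides. Dnmt3a was 3.49-fold lower in Dnmt3a KO (66.2 ± 4.85 against 231 ± 45.9 CPM, log2 -1.80 ± 0.20, edgeR adjusted p = 0.00067). Interferon genes of the panel did not pass, with log2 differences of -0.40 ± 0.16 for Gbp2 and 0.18 ± 0.17 for Irf1 (edgeR adjusted p 0.51 and 0.79). Nr4a1 was 2.29-fold higher (log2 1.20 ± 0.20, edgeR adjusted p = 0.011) and the kinase gene Sik1 1.97-fold higher (edgeR adjusted p = 0.048). Small structural RNAs were lower in Dnmt3a KO: the minor spliceosome RNAs Rnu11 (ENSMUSG00000077323.1, chromosome 4, 132270080 to 132270213) at 115 ± 16.3 against 677 ± 487 CPM and Rnu12 (ENSMUSG00000065176.1, chromosome 15, 83149644 to 83149794) at 67.3 ± 28.7 against 369 ± 222 CPM.

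Of the 33 genes that differed, 3 were higher and 30 lower in Dnmt3a KO, 22 were not protein coding, 17 of those lower were in the small RNA classes, and 1061 had an unadjusted p under 0.05. The strong excess of lower genes was not kept without WT infected 2, where WT infected 1 is the only WT infected library. In the fit without WT infected 1, which also leaves 1 WT infected library, lower genes still outnumbered higher ones. The small RNA classes, mitochondrial ribosomal RNAs included, took 11.8% of counts in both WT infected libraries, as stated above. The 4 lists that camera called were each lost with an estimated correlation (adjusted p = 0.65 for each): the GTPases (0 passed; 1 lower adjusted over the list alone; median -0.33), immediate early genes (1 higher and 2 lower; 6 and 2; 0.20), ribosomal proteins (2 lower; 5; -0.22) and mitochondrially encoded genes (1 lower; 2; -0.41). Under library totals these medians were -0.097, 0.42, 0.0049 and -0.19. Without WT infected 2 the calls of GTPases, immediate early and mitochondrially encoded genes also ended (camera adjusted p = 0.084, 0.080 and 0.45; medians -0.36, 0.32 and -0.075), and without Dnmt3a KO infected 2 those of GTPases and mitochondrially encoded genes (camera adjusted p = 0.099 and 0.21; medians -0.39 and -0.28). The GTPase median was -0.18 without WT infected 1, the ribosomal median -0.36 without WT infected 2, and the mitochondrial median -0.68 without Dnmt3a KO infected 1. Without WT infected 1 the log2 difference of Rnu11 went from -2.53 to -1.52 and that of Rnu12 from -2.37 to -1.61, and without WT infected 2 that of Rnu11 was -3.14. The count of 33 became 1 by edgeR with legacy=TRUE, the default of the installed version, 9 against a 1.5-fold threshold, 82 under voom and 136 with no filter. It became 1132 without WT infected 2, 10 without Dnmt3a KO infected 1 and 1 without Dnmt3a KO infected 2, and library totals alone, with a median shift of 0.23, gave 13 higher and 26 lower. Each of the 12 called named genes lost its call under at least 1 alternative, Dnmt3a without Dnmt3a KO infected 2 (adjusted p over 13 alternatives 1.7e-15 to 0.12), and Nr4a1, Sik1, Rnu11 and Rnu12 without Dnmt3a KO infected 1 and without Dnmt3a KO infected 2; Sik1 also lost it without WT infected 1, with DESeq2 size factors and at the thinned depth, and Rnu11 and Rnu12 under DESeq2 (highest adjusted p 0.28, 1.00, 0.15 and 0.17; lowest 1.6e-10, 0.00072, 1.2e-35 and 8.0e-27).

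Between the naive libraries, immediate early, neutrophil and myeloid genes stood higher in Dnmt3a KO. Nr4a1 was at 1089.5 CPM (95% interval 1052 to 1128) against 22.2 CPM (18.7 to 26.1) in WT naive, a 49.1-fold difference. Klf4, a regulator of monocytes, was at 97.3 CPM (86.2 to 109) against 3.90 CPM (2.53 to 5.76), and Mpo at 298 CPM (278 to 319) against 18.7 CPM (15.5 to 22.4). Cxcr4, the receptor that holds stem cells in the marrow, was lower, at 13 CPM (9.12 to 17.9) against 41.1 CPM (36.3 to 46.4). The interferon gene Gbp2 differed by log2 -0.28.

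With 1 library per group these differences have no replicate check. The list medians were 1.94 for immediate early genes, 3.71 for neutrophil markers and 0.61 for myeloid genes, each above all of 10000 random matched lists (percentile 100), as was that of NF-kB response genes at 0.41. Because members of a list may vary together, an extreme percentile between 2 libraries does not show an effect of genotype. Erythroid genes, at 0.43, lay at percentile 99.95. The GTPase median of -0.24 was at percentile 0.04, the stem cell median of -0.14 at 0.56, the interferon-stimulated median of -0.07 at 14, and the MHC class I median of 0.24 at 99.16. Under library totals these 4 medians were -0.37, -0.27, -0.20 and 0.10. Genes of the unfolded protein response (0.23, percentile 99.38), glycolysis genes (0.21, 98.84) and G2 and M phase genes (-0.19, 0.69) also lay outside the central 95% of random lists, with medians of 0.10, 0.08 and -0.32 under library totals. The list of Xist and Y chromosome genes had a median of -0.90 (percentile 0.01). Xist was at 569 CPM (551 to 588) in WT naive and 943 CPM (908 to 979) in Dnmt3a KO naive, and Uty at 30.0 CPM (25.9 to 34.5) and 11.9 CPM (8.24 to 16.6). Borrowing the spread of the infected pairs, edgeR called 53 genes higher and 0 lower, with 526 at an unadjusted p under 0.05; DESeq2 called 46 higher and 0 lower (187 unadjusted) and voom 85 higher and 0 lower (688 unadjusted). That count became 102 without WT infected 1 and 103 without WT infected 2, and 3 genes were lower in each case. In all 53 WT naive was the lowest of the 6 libraries. Of these 53, 43 were also higher with infection in WT, a comparison that uses the same WT naive library. Independent lists would share 0.756. Unchanged simulated groups gave 0 calls in either comparison and so shared 0, which sets no level for the overlap. Across genes the covariance of these comparisons was 0.145, not above the 0.197 of simulated unchanged groups (Pearson correlations 0.257 and 0.480). The simulated spread was set by expression level and not by gene, so these values cannot say how much overlap the shared library makes. Part of the overlap may come from that library.

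Averaged over naive and infected libraries, 63 genes differed by genotype, 55 higher and 8 lower in Dnmt3a KO, and 1041 had an unadjusted p under 0.05. The additive model gave 4 higher and 3 lower, and the excess of higher genes was also smaller without WT infected 2. Mpo (log2 1.92 ± 0.17, edgeR adjusted p = 5.6e-06) and Fos (log2 1.62 ± 0.15, edgeR adjusted p = 8.3e-06) were higher, and 17 of 28 immediate early genes passed (23 adjusted over the list alone; camera adjusted p = 0.042 with an estimated correlation). Neutrophil markers passed in 6 of 7 cases (7 adjusted over the list alone), with adjusted p = 0.15 with an estimated correlation. These averages carry the naive difference: Mpo stood at 177 ± 18.1 and 159 ± 2.80 CPM in the infected groups. The count became 120 without WT infected 1, 670 without WT infected 2, 34 without Dnmt3a KO infected 1, 33 without Dnmt3a KO infected 2, and 7 in the additive model.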

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

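For the patterns below, the depth tests and the regrouping of samples were written before their results were seen, and the other tests were chosen only after them. The infection responses of WT and Dnmt3a KO were set apart by the interaction test for 35 genes. Among these the log2 difference of the responses, Dnmt3a KO minus WT, was -2.64 for Btg2 and -2.64 for Fosb, -4.36 for Atf3, -3.34 for Fos, -4.42 for Nr4a1 and -2.87 for Socs3. For neutrophil and myeloid genes it was -4.09 for S100a9, -4.57 for Ngp (-3.91 without WT infected 1), -4.06 for Elane and -4.14 for Mpo, and it was -2.17 for Vegfa, a blood vessel growth factor gene, and -1.66 for Xist. The list of Xist and Y chromosome genes had a median log2 change with infection of -0.74 in WT and 0.57 in Dnmt3a KO. Xist itself rose in WT, so the list median does not describe it. With the animals' sex not given, the Xist value cannot be assigned to infection. Whether the sex of the animals differed between libraries, and bears on the other genes here, was not tested. Without Dnmt3a KO infected 2 the calls of Btg2, Elane, Socs3, Vegfa and Xist were lost (edgeR adjusted p 0.053, 0.30, 0.087, 0.93 and 0.098, each the highest over 11 alternatives, the lowest being 6.7e-11, 2.5e-05, 1.9e-09, 0.0003 and 8.7e-09). Vegfa and Xist also lost theirs without Dnmt3a KO infected 1 and under library totals, Vegfa under DESeq2, and Vegfa and Elane at the thinned depth, where the differences of Ngp, Elane and Socs3 were -5.74, -4.90 and -3.53.

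Camera set the responses apart for 9 lists, with median log2 differences of -1.76 for immediate early genes, -4.09 for neutrophil markers, -0.91 for myeloid progenitor genes, -0.39 for ribosomal proteins, -0.66 for mitochondrially encoded genes and 0.45 for G2 and M phase genes. The medians of -0.28 for MHC class I genes, -0.18 for quiescence genes and -0.26 for the unfolded protein response changed sign to 0.08, 0.18 and 0.10 when scaled by library totals alone, which put the median of all genes at 0.37. Under the same scaling the myeloid median was -0.55, the ribosomal -0.025, the mitochondrial -0.31 and that of G2 and M phase genes 0.81, and without WT infected 2 the call of mitochondrially encoded genes ended (camera adjusted p = 0.13). With an estimated correlation the call of the immediate early genes held (camera adjusted p = 0.045), and the lowest of the other 8 was 0.087.

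Immediate early genes were mostly lowest in WT naive, and higher in Dnmt3a KO naive as well as in infected libraries. The median log2 difference between the naive libraries was 1.91 with all libraries thinned to the shallowest (26 of 27 genes above 0). Thinning keeps each library's expected proportions, so it checks counting precision alone and leaves other traits that go with depth open. Infection alone leaves the unthinned 1.94 between uninfected libraries unexplained (27 of 28), though that value restates the pattern and is not separate evidence. Handling of the lone WT naive library stays open, since it was lowest for 25 of the 28 genes and its genotype has no second naive library. The labels' genotype is the biological alternative, and the same lack of a second library keeps it untested. These genes also respond to dissociation, so a difference in cell preparation may be a candidate explanation.

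Neutrophil and myeloid genes were likewise lowest in WT naive. The median difference of the 7 neutrophil markers stayed at 3.52 after thinning (3.71 before). As above, thinning checks counting precision alone and leaves other traits that go with depth open. Mature neutrophils stay open: late-stage transcripts (Retnlg, Mmp8, Mmp9, Cxcr2 and Ly6g) came to at most 1.32% of the counts of S100a8, S100a9, Camp, Ngp and Ltf in the other 5 libraries and 6.71% (10 of 149) in WT naive, but the share expected of such cells was assumed, not measured here. Granulocyte precursors stay open too, because the gain of Prtn3 over WT naive as a percent of that of Elane had a median of 11.6 and ran from -43.4 to 46.9. A response of the stem cells themselves in Dnmt3a KO and on infection may also apply and was not tested.

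Small structural RNAs were higher in WT infected than in Dnmt3a KO infected libraries, with a median log2 difference of -0.74 over 175 genes, 139 of them below 0. The median was -0.83 over 117 genes after thinning. Thinning keeps each library's expected proportions, so it checks counting precision alone and leaves other traits that go with depth open. The share of counts, which includes the mitochondrial ribosomal RNAs, was 11.8% in the WT infected libraries, the shallowest, and 4.97% in Dnmt3a KO infected 2, the deepest. A genotype effect in both states stays open: the naive libraries differed by -0.41 in the same direction, while the share of counts went the other way (6.45% in Dnmt3a KO naive, 5.4% in WT naive). RNA or library quality of the WT infected samples may be a candidate source, with shares of at least 11.8% against at most 6.50% elsewhere, and it cannot be told apart from the group because both WT infected libraries share it.

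For the genotype effect over both states, the additive model called 7 genes, and 2 of the 10 splits of the 6 libraries into 3 and 3, the real one included, gave as many; 10 splits are too few for a share under 0.05. The highest other split called 199 genes, and it set WT naive, WT infected 1 and Dnmt3a KO naive against the rest. With infection in the model, that split parts WT infected 1 from the other 3 infected libraries, which points to a structure of the samples.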

How the results depend on the processing

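Counts thinned to the shallowest library, the voom fit with the submitters' filter, library totals for named genes, gene lists without 1 naive library, and leaving out naive libraries outside the genotype comparison of infected samples were chosen after the data were seen. Over 199 results for named genes, 2105 values under alternatives kept their side of the threshold, 179 lost the call and 22 gained one. Direction reversed in 0 values with a call in the main or the alternative fit. Any change of direction without a call in either fit was counted among the 2105. Most losses came without Dnmt3a KO infected 2 (60 of 199) or Dnmt3a KO infected 1 (39), where the spread then rests on the WT infected pair by construction; without WT infected 1 or WT infected 2 it rests on the Dnmt3a KO pair. Over 80 called list results, 63 lost the call with an estimated correlation, 44 under fry and 0 under DESeq2 size factors, and 20 of 20 kept it without WT naive and without Dnmt3a KO naive where that library was not compared. Depth limits the WT infected libraries most, at 1279856 and 1693884 counts. The cause was not tested where none is given.

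Genes changed by infection in WT numbered 182, those in Dnmt3a KO 57, those for genotype among infected libraries 33 and among naive libraries 53, those for the difference of responses 35, for the mean infection effect 226 and for the mean genotype effect 63. In that order of comparisons, edgeR with legacy=TRUE gave 115 for infection in WT, 1 for genotype among infected libraries, 14 for the difference, 138 for mean infection and 40 for mean genotype. With no filter the numbers were 287, 117, 136, 92 and 74 for the first 5 comparisons, and 128 for mean genotype. Infection then gave 249 higher and 38 lower in WT, and 86 higher and 31 lower in Dnmt3a KO. Against a 1.5-fold threshold, which asks for a larger change, they were 100 for infection in WT, 9 for genotype among infected libraries, 21 for the difference, 95 for mean infection and 35 for mean genotype. Voom gave 95 for infection in Dnmt3a KO, 82 and 85 for genotype among infected and naive libraries, 73 for the difference and 107 for mean genotype, and with the submitters' filter 92, 79, 84, 75 and 113. The compared groups alone gave 214 for infection in Dnmt3a KO, thinned counts 20 for the difference, and the additive model 7 for mean genotype.

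Leaving out 1 library at a time gave 96 (without Dnmt3a KO infected 2) to 1217 (without WT infected 2) for infection in WT, 25 to 159 in Dnmt3a KO, 1 to 1132 for genotype among infected libraries, 40 to 103 among naive ones, 8 to 168 for the difference, 100 to 990 for mean infection and 33 to 670 for mean genotype, with the extremes from the same 2 libraries (40 also without Dnmt3a KO infected 1). The correlation of the infection responses across genes, 0.292, was 0.0164 with no filter and 0.356 at a mean of at least 5 CPM, and 0.179 (without WT infected 2) to 0.284 with 1 library left out.

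The replicate numbers were not shown to pair the libraries: the differences of replicate 2 from replicate 1 had a correlation of 0.0263 across genes between the genotypes, from 2 pairs. With the replicate number as a block the counts were 279, 110, 109, 96, 89, 340 and 138 in the order of comparisons above, and 106 for genotype in the 4 infected libraries alone. The block ended the call of 1 list and made 3 named genes pass, Mpo and Hlf with infection in Dnmt3a KO (both lower) and Hist1h2ac in the difference of responses.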

Other observations

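The list tests here were planned, and Btg2, Hes1, Egr1 and the markers of other blood cells are named after their values were seen. Genes of the quiescence list moved both ways in WT with infection: 6 of 20 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.13 that was -0.19 under library totals and -0.02 without WT infected 1, and adjusted p = 0.13 with an estimated correlation. Those that rose were Nr4a1, Klf2, Btg2, Hes1 and Egr1, transcription regulators that also answer acute stimulation, and Cdkn1a, an inhibitor of cyclin-dependent kinases. Those that fell were Txnip and Ndn, an imprinted growth suppressor gene. Calls of Txnip, Ndn and Cdkn1a were lost without Dnmt3a KO infected 2 (edgeR adjusted p 0.065, 0.19 and 0.10, the highest over 12 alternatives, the lowest being 1.2e-05, 0.0092 and 0.00031), those of Ndn and Cdkn1a also without Dnmt3a KO infected 1 and at the thinned depth, and that of Ndn under DESeq2 and under voom with either filter. Without WT infected 2 the log2 change of Ndn was -3.69 in place of -2.96. In Dnmt3a KO 2 of the 20 fell (5 adjusted over the list alone), Nr4a1 and Txnip, and 0 rose, with adjusted p = 0.13 with an estimated correlation. That call of Txnip was lost without Dnmt3a KO infected 1 and without Dnmt3a KO infected 2 (edgeR adjusted p over 12 alternatives 1.1e-05 to 0.43).

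Genes of the unfolded protein response had a median log2 change of 0.57 with infection in WT (0.25 under library totals), where Hspa5, the main chaperone of the endoplasmic reticulum, and Atf3 rose (9 of 20 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). In Dnmt3a KO the median was 0.25 (0.29 under library totals) and 0 of the 20 passed (adjusted p = 0.37 with an estimated correlation). Among cell cycle genes 0 passed in either genotype over all genes by edgeR: S phase medians were 0.28 in WT (-0.04 under library totals) and 0.32 in Dnmt3a KO, with adjusted p = 0.22 and 0.14 with an estimated correlation, and G2 and M phase medians were -0.08 and 0.38 (camera adjusted p = 0.52 in WT, and adjusted p = 0.13 with an estimated correlation in Dnmt3a KO). Oxidative phosphorylation genes had medians of 0.18 in WT (-0.14 under library totals) and 0.29 in Dnmt3a KO, with adjusted p = 0.22 and 0.14 with an estimated correlation. Without WT infected 2 the S phase call in WT ended, and without WT infected 1 that of oxidative phosphorylation (camera adjusted p = 0.072 and 0.15). Imprinted genes had medians of -0.53 in WT (-0.30 without WT infected 1, -0.89 without WT infected 2 and -0.85 under library totals) and -0.49 in Dnmt3a KO, where Ndn fell in WT and 4 of 11 fell in Dnmt3a KO adjusted over the list alone, with adjusted p = 0.22 in both with an estimated correlation.

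With infection in Dnmt3a KO camera called erythroid genes (median -0.28; 1 of 12 fell, 2 adjusted over the list alone) and endothelial and stromal markers (median -0.75; 0 of 6 passed, 1 fell adjusted over the list alone), with adjusted p = 0.37 and 0.30 with an estimated correlation. The endothelial call also ended without Dnmt3a KO infected 1 and without Dnmt3a KO infected 2 (camera adjusted p = 0.058 and 0.066). In WT neither list was called (medians 0.02, -0.30 under library totals, and -0.66). NF-kB response genes had medians of 0.34 in WT (0.02 under library totals, 0.22 without WT infected 1, 0.51 without WT infected 2; 1 of 21 rose) and 0.33 in Dnmt3a KO (0 of 21; call ended without Dnmt3a KO infected 2, median 0.20), with adjusted p = 0.13 and 0.24 with an estimated correlation. Ribosomal proteins in WT had a median of 0.28 (-0.04 under library totals; 2 of 84 rose), and mitochondrially encoded genes in Dnmt3a KO one of -0.42 (0 of 10 passed; call ended without Dnmt3a KO infected 2, median -0.22), with adjusted p = 0.24 and 0.41 with an estimated correlation. Camera did not call megakaryocyte genes in either genotype (medians 0.06 in WT, -0.25 under library totals, and 0.10 in Dnmt3a KO), nor lymphoid progenitor genes (0.03, -0.28 under library totals with a mean of -0.25, and -0.01, 0.04 under library totals with a mean of 0.07), p53 targets (0.03, -0.29 under library totals, and 0.08) or DNA methylation genes (0.15, -0.17 under library totals, and -0.04). Of the 12 measured markers of T and NK cells (Lck, Thy1, Ccl5), B and plasma cells (Xbp1, Cd79b, Sdc1), macrophages (Slc40a1, Vcam1, Axl, Cd68) and mast cells and basophils (Cpa3, Kit), 0 passed by edgeR over all genes with infection in WT or Dnmt3a KO. The smallest adjusted p in WT was 0.22, for Xbp1 (log2 0.78), and in Dnmt3a KO 0.82, for Slc40a1 (log2 -1.90).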
